A study of Mus musculus with 8 samples.

How the data were processed

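Gene expression was measured on 8 microarrays of total RNA from sorted mouse skin tumour cells, in 4 groups of 2 arrays. The values were deposited as 2 tables, each holding 4 arrays of a different Affymetrix mouse genome array type: the Twist1 deletion arrays with their controls on the standard type, and the Twist1/p53 deletion arrays with their controls on a type that carries perfect-match probes alone. Per the labels, RNA was extracted with a column kit for small cell numbers, labelled with biotin and hybridised at an array facility. The summarisation and normalization software is not given in the sources used here.

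The deposited values are on a log2 scale, as read from the values themselves, since no label or header states it: they run from 2.76 to 14.45 with no negative value, and each probe set has 1 value per array. The authors had brought the arrays of a table to nearly the same distribution, with array medians between 5.42 and 5.44 in the Twist1 table and between 4.81 and 4.82 in the Twist1/p53 table. Values were not centred per probe set. Scanner files were not used here, so background and spot quality could not be examined, and the number of arrays limits the precision. The 2 tables were normalized separately, and every difference was taken within a table. A level in one table is not comparable with a level in the other.

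Probe sets were named through the platform annotation, with symbols compared with the RefSeq gene table of assembly GRCm38.p6 by Entrez number. In the Twist1 table, 34945 of 45101 probe sets had 1 gene symbol, 932 had several and 9160 had none listed, next to 64 control probe sets. In the Twist1/p53 table, 28864 of 45083 had 1 gene symbol, 551 had several and 15564 had none listed, next to 104 control probe sets. Probe sets with several symbols or none were left out of the gene tests. No coordinates are given, because the build behind the array designs is not given in the sources used here. The level of the p53 gene itself is not reported here. Each gene was represented by its probe set with the highest mean over the arrays of the table, and genes whose probe set mean lay under the 20th percentile were left out, which kept 14554 genes in the Twist1 comparison and 13667 in the Twist1/p53 comparison.

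Each deletion was compared with its own controls by limma's lmFit and eBayes with an intensity trend, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Log2 fold changes are deletion minus control, and errors are moderated standard errors (SE) or the 2 single array values. The difference between the 2 deletions was fitted over all 8 arrays as the Twist1/p53 change minus the Twist1 change, over 13296 genes matched by probe set. There the probe set of a gene was chosen by its mean rank over both tables. The Twist1 or Twist1/p53 change of a gene can therefore differ from that in its own comparison. A total of 37 gene lists were fixed before the data were examined, and 36 with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry served as alternatives, and none of the list calls at the preset correlation held with the estimated one. With an estimated correlation, camera takes its degrees of freedom from the arrays rather than the genes. With 2 arrays per group hardly any list can pass there, so not passing does not show that a list was unchanged. The preset value in turn can be too low for lists whose genes vary together. Members were counted as risen or fallen after adjustment over all genes, and also adjusted over the list alone.

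The genes named follow a rule fixed beforehand: Twist1 and Cdkn1a always, the 10 largest rises and falls among called genes whose groups did not overlap, filled where fewer passed by the largest changes with an unadjusted p under 0.01 and groups that did not overlap, and of each list described the members with the highest and lowest moderated t. Unnamed transcripts and sex-linked genes were skipped in the ranking. Not every list member that the rule picks is named, and some of those left out go against the direction of their list. Further genes are named where stated. The alternatives were quantile normalization, median centring, no filter or a filter at the 50th percentile, the mean over the probe sets of a gene, no intensity trend, a robust fit, the replicate number as a block, leaving out each array, other thresholds and, for the difference, separate fits and rescaled tables. A fit without the genes of the X and Y chromosomes was added after the data had been seen.

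The fits were tested on simulated arrays with the real gene means and a spread drawn from the fitted model, in which 200 genes were changed. Both groups had the same spread, whereas the real deletion arrays spread more than their controls. At a log2 change of 1, 7.46% of the changed genes were called in the Twist1 comparison (14554 genes), 34.3% in the Twist1/p53 comparison (13667 genes) and 11.9% in the difference (13296 genes). At a log2 change of 2 the shares were 86.6%, 89.6% and 68.7%, and at 4 they were 98.5%, 95.5% and 97.0%. In the same simulations 7, 5 and 5 unchanged genes were called, and no changed gene was called with the wrong sign. With no gene changed, 0, 1 and 0 genes were called in these fits, and 0 gene lists in each. Genes were simulated independently of each other, so this list result does not cover lists whose genes vary together. The analysis used R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9.

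Same-numbered arrays were not paired by any label. The labels give each array an identification number of its own without saying that these are separate animals, so p-values measure only the spread between these samples, which may be technical. No pair of arrays held identical tables. The mice were littermates of a mixed background, per the labels.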

Results

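Tumours were induced in mouse skin with the carcinogen DMBA and the tumour promoter TPA, and the tumour-bearing mice received 5 doses of 2 mg tamoxifen. In the deletion groups, tamoxifen activates CreER, a recombinase fused to a part of the estrogen receptor and expressed from the keratin 14 promoter, which removes floxed genes in basal epithelial cells. Tumour epithelial cells were then sorted as live cells carrying the epithelial surface protein Epcam and lacking lineage markers, with antibodies to CD45 on leukocytes, CD31 on endothelial cells and CD140a on fibroblasts. The 2 deletions studied, each with its own floxed controls without Cre and 2 arrays per group, were deletion of Twist1, a basic helix-loop-helix transcription factor, and deletion of both Twist1 and p53. The comparisons ask what changes in tumour epithelial cells after Twist1 is lost, and which changes differ when p53 is lost as well, a design that the sample titles call a rescue. The deposited log2 values ranged from 2.81 to 14.45 in the Twist1 table and from 2.76 to 13.24 in the Twist1/p53 table.

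Twist1 was lower in both deletions. In the Twist1 comparison its probe set read 5.20 and 7.18 in the controls and 3.81 and 3.90 in the deletion arrays, a log2 fold change of -2.33 (SE 0.64, n = 2 per group) that did not pass the test (limma, adjusted p = 0.50). In the Twist1/p53 comparison it fell from 6.15 and 6.04 to 4.82 and 5.01, a log2 fold change of -1.19 (SE 0.14, adjusted p = 0.041), although without either control array it no longer passed (-1.13 without control 1 and -1.24 without control 2). Whether this probe set lies in the deleted part of the gene is not known from the sources used here. Cdkn1a, which encodes the p53-induced cell-cycle inhibitor p21, differed by 0.28 (SE 0.16, adjusted p = 0.62) in the Twist1 comparison. In the Twist1/p53 comparison it read 12.02 and 12.07 in the controls and 11.97 and 12.08 in the deletion arrays.

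Genes that mark the sex of a mouse separated the groups in both comparisons. Xist, which is transcribed from the inactive X chromosome of females, read 11.81 and 11.88 in the Twist1 controls and 6.98 and 6.07 in the Twist1 deletion arrays. In the Twist1/p53 comparison Xist read 10.92 and 10.89 against 4.06 and 3.66. The Y-linked gene Eif2s3y went the other way, with 3.62 and 3.52 against 9.42 and 9.35 in the Twist1 comparison and 3.52 and 3.26 against 8.90 and 9.27 in the Twist1/p53 comparison. The labels give no sex, and within each comparison a sex difference and the deletion cannot be told apart. The same holds for the presence of Cre, which the controls lack. Of the 5 genes called in the Twist1 comparison 3 were sex-linked (Xist, Eif2s3y and Uty), whereas 240 of the 246 called in the Twist1/p53 comparison were autosomal.

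**Figure D1:**
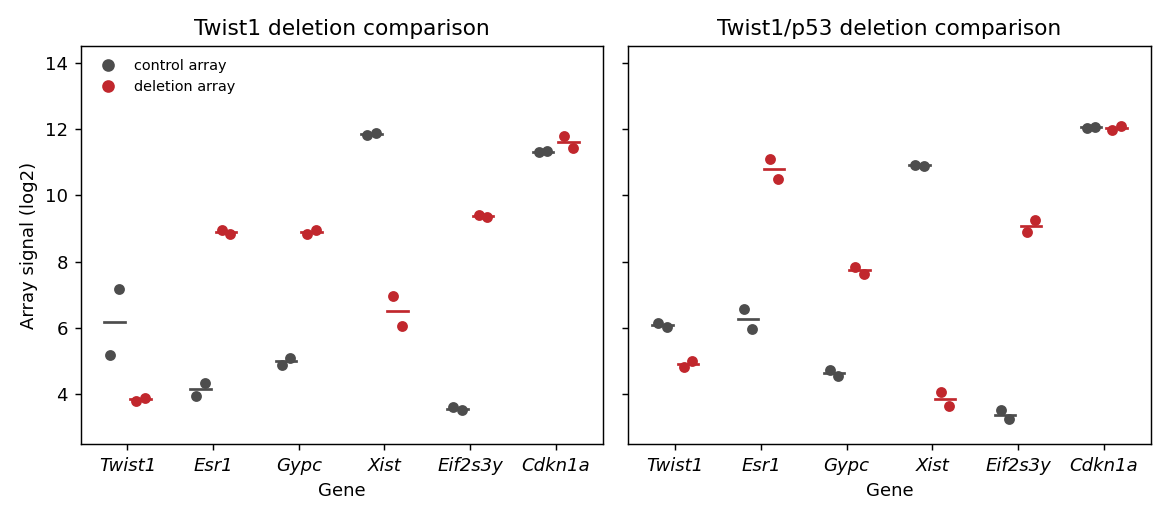
Array signal on the log2 scale (vertical axis) of 6 genes (horizontal axis) in the Twist1 comparison (left) and the Twist1/p53 comparison (right), with 1 point per array, control arrays in grey, deletion arrays in red and a bar at each group mean (n = 2). Esr1 and Gypc are higher in all 4 deletion arrays than in their controls, and Xist and Eif2s3y separate the groups in opposite directions in both comparisons.

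Deletion of Twist1 alone changed few genes past the threshold. Apart from the sex-linked genes, 2 genes passed. The signal of the estrogen receptor gene Esr1 rose 26.6-fold, from 3.96 and 4.34 to 8.94 and 8.83 (log2 fold change 4.73, SE 0.21, adjusted p = 0.020), in 1 of its 3 probe sets, while the other 2 differed by 0.32 and -0.24. Gypc, a membrane glycoprotein best known from red blood cells, rose 14.9-fold, from 4.88 and 5.11 to 8.83 and 8.94 (log2 fold change 3.89, SE 0.18, adjusted p = 0.020). In total 4 genes rose and 1 fell among 14554. The next genes by size did not pass. Nppb, the precursor of B-type natriuretic peptide, read 10.53 and 10.12 in the controls and 7.06 and 6.40 in the deletion arrays (log2 fold change -3.59, SE 0.28, adjusted p = 0.10). Pparg, a nuclear receptor of adipocyte and sebocyte differentiation, read 4.43 and 4.49 against 7.82 and 6.89 (2.89, SE 0.34, adjusted p = 0.22). Pde3b (3.76), Aldh3a1 (2.53), Calcb (2.51), Dlgap1 (2.48), Mir1931 (2.46), Rgcc (2.25) and Defb6 (2.19) were also higher by these log2 fold changes, with adjusted p between 0.099 and 0.45. Pou2af1 (-2.09), Stfa2l1 (-2.09), Ifi204 (-1.99), Clrn3 (-1.91), Vwa2 (-1.89), Lgi2 (-1.88), Dpp4 (-1.83), Rgs7bp (-1.74) and Krt1 (-1.81), a keratin of the differentiating epidermal layers, were lower, with adjusted p between 0.21 and 0.47. The groups did not overlap for 42.5% of genes, against 33.3% by chance, and 1334 genes had an unadjusted p under 0.05 against 728 by chance. Without control 1 or control 2 no gene passed in limma (523 and 559 genes at an unadjusted p under 0.05), and without deletion array 1 or 2 the count was 56 or 40.

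Among the 36 lists tested after Twist1 deletion, the cell-cycle lists were lower than other genes. All 27 measured DNA replication genes and 31 of 32 genes of the G2 and M phases of the cell cycle had lower means in the deletion arrays, with median log2 fold changes of -0.34 and -0.45. The groups did not overlap for 21 and 27 of them, where 33.3% would do so by chance and 42.5% of all genes did. Nusap1, a spindle protein, was lower by -0.69 (SE 0.14) and the cyclin Ccna2 by -0.56 (SE 0.12), while Foxm1 (-0.05) and Ckap2 (0.03) were close to their controls. Of the replication genes, Gins1 was lower by -0.58 (SE 0.17) and Rrm1, a subunit of ribonucleotide reductase, by -0.50 (SE 0.12), and Pcna by -0.10 (SE 0.14). No member passed on its own, over all genes or adjusted over the list alone. Camera gave adjusted p = 1.57e-11 for the G2/M list and 4.66e-08 for the replication list, and each had adjusted p = 0.54 with an estimated correlation. In the same arrays, the poly-A spike-in probe sets, which are added to the RNA before labelling, averaged 8.22 and 9.14 in the controls and 9.49 and 10.53 in the deletion arrays. Signs of RNA quality separated the same groups: the 3' probe sets of Gapdh exceeded the 5' ones by 0.04 and 0.03 in the controls and 0.22 and 0.30 in the deletion arrays, and those of Actb by 0.63 and 0.63 against 0.95 and 0.79. They stand beside every list of this comparison, including those below.

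The lists of EGFR ligands and MAPK targets and of E proteins and Id genes were higher after Twist1 deletion. Of 17 EGFR and MAPK genes 15 were higher, with a median of 0.26, and 2 rose adjusted over the list alone (camera adjusted p = 1.17e-05, fry adjusted p = 0.011, and adjusted p = 0.54 with an estimated correlation). Dusp4, a phosphatase induced by MAPK signalling, was higher by 1.81 (SE 0.27) and Spry1, an inhibitor of receptor tyrosine kinase signalling, by 0.88 (SE 0.16). All 7 E protein and Id genes were higher, with a median of 0.56, and 4 rose adjusted over the list alone (camera adjusted p = 1.65e-04, and adjusted p = 0.54 with an estimated correlation). Id proteins bind E proteins, which are also the partners of Twist1. Id4 was higher by 1.88 (SE 0.48) and Id2 by 1.81 (SE 0.31). The E protein genes Tcf3 (0.09, SE 0.14) and Tcf12 (0.13, SE 0.19) were close to their controls. No member of any list but the sex-linked one passed over all genes.

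Further lists higher after Twist1 deletion were those of tumour-propagating and follicle stem cells, hypoxia, simple keratins, NRF2 and p53 targets, sebocytes, adipocytes and immediate early genes. Of the 22 stem cell genes 17 were higher (median 0.44), among them Sox9 (1.03, SE 0.19), while the VEGF co-receptor Nrp1 was lower (-1.11, SE 0.23). Adjusted over the list alone, 3 rose and 1 fell. Of 22 hypoxia and glycolysis genes 15 were higher (median 0.15), with carbonic anhydrase Car9 (1.47, SE 0.20) and Ndrg1 (0.64, SE 0.11) highest by moderated t, and 4 rose adjusted over the list alone. Krt8 and Krt18, keratins of simple epithelia, were higher by 2.09 (SE 0.33) and 2.39 (SE 0.64). All 6 genes of their list had higher means (median 1.46), but Krt19 was close to its controls (0.001, SE 0.18). The groups did not overlap for 3 of the 6, against 42.5% of all genes, and 2 rose adjusted over the list alone. Camera gave these 3 lists adjusted p = 0.0010 each, and adjusted p = 0.54 each with an estimated correlation. Krt13, a keratin of internal stratified epithelia, varied more within groups than between them (4.61 and 8.40 against 9.92 and 6.05). All 14 NRF2 targets were higher (median 0.35, adjusted p = 0.0010, and adjusted p = 0.58 with an estimated correlation), among them Taldo1 (0.40, SE 0.14), an enzyme of the pentose phosphate pathway. Txnrd1, a thioredoxin reductase, was at 0.32 (SE 0.13) but at -0.00473 with the mean over its probe sets. The groups did not overlap for 2 of the 14, against 42.5% of all genes, and the list did not pass without deletion array 1 (median 0.03). Of the 33 p53 targets 23 were higher, with a median of 0.22 (camera adjusted p = 0.0027, and adjusted p = 0.63 with an estimated correlation), including Abhd4 (0.83, SE 0.21) and Mdm2 (0.55, SE 0.17), the ubiquitin ligase of p53, while Ak1 (-0.61, SE 0.21) and Phlda3 (-0.34, SE 0.19) were lower. The p53 target list had a median of 0.002 without deletion array 1 and then did not pass.

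Pparg, a member of both the sebocyte and the adipocyte list, was the marker with the largest difference. The 9 sebocyte markers had a median of 0.30 (adjusted p = 0.011) and the 6 adipocyte markers one of 0.43 (adjusted p = 0.035), each with adjusted p = 0.54 with an estimated correlation and 1 rise adjusted over the list alone. Means were higher for 8 of the 9 and all 6, but groups did not overlap for only 3 and 1, against 42.5% of all genes. Scd3 (0.05), Cidec (0.08) and Plin4 (0.16) changed little, and Dgat2 was lower (-0.21, SE 0.29). The lipid droplet gene Cidea was higher by 1.93 (SE 0.78), and Fabp4, a fatty acid binding protein, varied widely within groups (8.96 and 12.01 against 12.84 and 9.75). The immediate early list had a median of 0.11 (adjusted p = 0.035, and adjusted p = 0.54 with an estimated correlation), and Egr2 was higher by 1.47 (SE 0.58). Cholesterol synthesis genes were lower (15 of 19, median -0.21, adjusted p = 0.035, and adjusted p = 0.63 with an estimated correlation), with Fdps at -0.67 (SE 0.12) and the squalene epoxidase gene Sqle at -0.66 (SE 0.18). Without deletion array 2 the sebocyte (0.11), adipocyte (0.21), immediate early (0.07), cholesterol (-0.05) and stem cell (0.30) lists did not pass at these medians. Without control 1 the same holds for the cholesterol (-0.24) and adipocyte (0.19) lists, and without control 2 for the cholesterol (-0.16) and immediate early (-0.01) lists. Markers of leukocytes (median 0.04, adjusted p = 0.46), endothelial cells (0.06, adjusted p = 0.25), fibroblasts (0.07, adjusted p = 0.25), melanocytes (0.17, adjusted p = 0.15) and muscle (0.08, adjusted p = 0.63) did not pass. EMT and mesenchymal genes, a group that Twist1 can activate, did not pass either (median -0.05 over 18 genes, adjusted p = 0.46). Cells without Epcam were removed by the sort in every group, so this result does not cover them.

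After deletion of Twist1 together with p53 the largest rises were mostly those of interferon-induced genes. On the fixed lists 15 of 21 interferon genes rose and 4 of 33 p53 targets fell, with 1 fall each among 24 epidermal differentiation, 18 cholesterol synthesis, 14 fibroblast and 10 Notch pathway genes. The rises led with Ifi27l2a, which went 70.6-fold up from 5.13 and 4.93 to 11.07 and 11.28 (log2 fold change 6.14, SE 0.16, limma adjusted p = 0.0049), and the antiviral enzyme gene Rsad2, 42.2-fold up from 4.71 and 5.03 to 10.16 and 10.38 (5.40, SE 0.18, adjusted p = 0.0080). Rtp4 (5.20), the T-cell chemoattractant Cxcl9 (4.72), Oasl2 (4.72), Ifit1 (4.37), the chemokine Ccl8 (4.33) and the ISG15 protease Usp18 (3.97) rose as well, with SE between 0.18 and 0.24. Outside this group Esr1 rose by 4.52 (SE 0.30), in the probe set that also rose after deletion of Twist1 alone, and Cep85 rose by 4.27 (SE 0.48). The metallothionein Mt4 of differentiating squamous epithelium fell 17.6-fold, from 10.85 and 10.91 to 7.08 and 6.40 (log2 fold change -4.14, SE 0.25, adjusted p = 0.012). Rgs5, a regulator of G protein signalling, fell by 3.19 and Igfbp2, which binds insulin-like growth factors, by 3.08 on the log2 scale. The other largest falls were those of Otop3 (-2.95), Dpysl3 (-2.94), Gdpd3 (-2.80), the collagen VI chain Col6a1 (-2.70), Usp39 (-2.69), the hyaluronan-binding gene Cemip (-2.59) and Lor (-2.55), which encodes the cornified envelope protein loricrin. In total 161 genes rose and 85 fell among 13667, the groups did not overlap for 54.3% of genes against 33.3% by chance, and 2897 genes had an unadjusted p under 0.05 against 683 by chance. The 2 control arrays were much closer to each other (SD of their differences 0.19) than the 2 deletion arrays (0.47). Without control 1 or control 2 no gene passed in limma (1027 and 1141 genes at an unadjusted p under 0.05), and without deletion array 1 or 2 the count was 3775 or 3363.

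The interferon list showed the largest shift of the 36 lists after Twist1/p53 deletion. Of its 21 measured members 15 rose over all genes and 21 adjusted over the list alone, none fell, and the median log2 fold change was 2.17 (camera adjusted p = 1.07e-24, and adjusted p = 0.56 with an estimated correlation). The members with the lowest t were Mx1 (0.79, SE 0.23, adjusted p = 0.16) and Oas2 (1.82, SE 0.47, adjusted p = 0.14). Fry gave the list an adjusted p of 0.075. Of 19 leukocyte markers 2 rose, both of antigen presentation, Cd74 (2.40, SE 0.29) and H2-Ab1 (1.90, SE 0.16), while H2-Aa of the same class was higher by 1.69 (SE 0.29, adjusted p = 0.075) and the monocyte gene Cd14 by 1.34 (SE 0.42, adjusted p = 0.18). The lymphocyte genes Cd3e (-0.68, SE 0.10, adjusted p = 0.062) and Cd52 (-0.43, SE 0.14, adjusted p = 0.19) were lower, while Cd3g (0.05, SE 0.10) and Cd3d (0.07, SE 0.14) were not. The Cd3 genes read between 4.24 and 5.14, close above the filter level of 3.98. Adjusted over the list alone 3 rose and 1 fell. The median of the leukocyte list was 0.10 (camera adjusted p = 0.035, and adjusted p = 0.57 with an estimated correlation), and it did not pass without deletion array 1 (median 0.04), with quantile normalization or without the filter (both 0.07). Of 25 cytokines and chemokines 1 rose, the skin chemokine Ccl27a (2.12, SE 0.15). In that list Il6 was higher by 1.60 (SE 0.27, adjusted p = 0.072), Il18 was lower by -2.35 (SE 0.42, adjusted p = 0.079), and the median was 0.38 (camera adjusted p = 0.0028, and adjusted p = 0.66 with an estimated correlation). Adjusted over the list alone 5 rose and 1 fell.

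The p53 target list was lower after Twist1/p53 deletion, with a median of -0.62 over 33 genes (camera adjusted p = 1.34e-04, and adjusted p = 0.56 with an estimated correlation). Over all genes 4 fell and none rose, and adjusted over the list alone 13 fell and 1 rose. Aen, an exonuclease that p53 induces, fell from 10.92 and 10.83 to 9.66 and 9.61 (log2 fold change -1.24, SE 0.08, adjusted p = 0.017), and Mdm2 fell from 10.55 and 10.61 to 9.77 and 9.73 (-0.83, SE 0.08, adjusted p = 0.031). The other 2 that fell, chosen after their values were seen, were Ccng1 (-1.13, SE 0.12) and Ptp4a3 (-1.68, SE 0.19). Abhd4 was higher by 0.67 (SE 0.13, adjusted p = 0.085). Epidermal differentiation genes were lower in 20 of 24 cases, with a median of -0.99 (camera adjusted p = 2.80e-04, and adjusted p = 0.83 with an estimated correlation). Of these Lor fell over all genes and 3 fell adjusted over the list alone, Evpl, a cornified envelope protein, was lower by -0.93 (SE 0.18), and Sprr2a1 was higher by 0.77 (SE 0.19). Ribosome biogenesis genes were lower in 19 of 21 cases with a median of -0.21 (adjusted p = 3.14e-04, and adjusted p = 0.66 with an estimated correlation), among them Cad (-0.74, SE 0.12) and Dkc1 (-0.48, SE 0.07). The DNA replication (median -0.05, adjusted p = 0.999) and G2/M lists (median -0.15, adjusted p = 0.073) did not pass.

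Several lists that were higher after deletion of Twist1 alone were also higher after Twist1/p53 deletion. Of 22 hypoxia and glycolysis genes Bnip3, a mitophagy receptor, rose by 1.64 (SE 0.11) and Egln3, a prolyl hydroxylase of the hypoxia response, by 0.94 (SE 0.08), and 7 rose adjusted over the list alone (median 0.14, camera adjusted p = 2.28e-04, and adjusted p = 0.56 with an estimated correlation). Of 16 EGFR and MAPK genes the growth factor gene Tgfa rose by 1.26 (SE 0.16) and Dusp6 by 0.94 (SE 0.09), while Etv4 (-0.91, SE 0.14) and Ereg (-0.61, SE 0.12) were lower, with 6 rises and 2 falls adjusted over the list alone (median 0.19, camera adjusted p = 0.0078, and adjusted p = 0.56 with an estimated correlation). Of 21 tumour-propagating and stem cell genes Sox4 rose by 2.47 (SE 0.17), Nrp1 was lower by -1.53 (SE 0.37), and 5 rose and 1 fell adjusted over the list alone (median 0.52, camera adjusted p = 3.63e-04, and adjusted p = 0.56 with an estimated correlation). The E protein and Id list had a median of 0.74 (camera adjusted p = 0.040, and adjusted p = 0.76 with an estimated correlation). Of its 7 genes 5 were higher, among them Id2 (1.60, SE 0.26) and the E protein gene Tcf4 (0.97, SE 0.16). Id1 (-0.56, SE 0.39) and the E protein gene Tcf3 (-0.11, SE 0.19) were lower. The sebocyte list had a median of 0.40 (camera adjusted p = 0.045, and adjusted p = 0.82 with an estimated correlation). Of its 8 genes 7 were higher, among them Elovl3 (0.73, SE 0.19). Mc5r was close to its controls (0.002, SE 0.08), and Dgat2 was lower (-0.64, SE 0.29). The E protein and Id list did not pass without deletion array 1 (median 0.26) or with the mean over the probe sets of a gene (0.52). The sebocyte list did not pass without deletion array 2 (0.25) or control 2 (0.39), with quantile normalization (0.37) or with the mean over probe sets (0.28).

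The activated keratinocyte, secretory and unfolded protein lists were higher too after Twist1/p53 deletion. The calgranulins S100a8 and S100a9, which keratinocytes make in inflamed skin, were higher by 2.27 (SE 0.31) and 2.11 (SE 0.29), each with adjusted p = 0.055. The keratins Krt16 (-0.22, SE 0.08) and Krt6b (-0.20, SE 0.11) of the same list were not higher. The activated keratinocyte list had a median of 0.39 over 11 genes with 3 rises adjusted over the list alone (camera adjusted p = 0.034, and adjusted p = 0.83 with an estimated correlation) and did not pass without deletion array 2 (0.15). The collagenase gene Mmp13 was higher by 2.34 (SE 0.45) in the senescence and secretory list, whose median was 0.57 over 14 genes with 4 rises adjusted over the list alone (camera adjusted p = 0.0024, and adjusted p = 0.76 with an estimated correlation). In that list 11 genes were higher and 3 lower, among the latter Cdkn2a (-0.34, SE 0.37) and Cdkn2b (-0.20, SE 0.15). In the unfolded protein response list the pseudokinase gene Trib3 rose by 1.41 (SE 0.15) and Herpud1 was higher by 0.62 (SE 0.12), with a median of 0.16 over 17 genes (camera adjusted p = 0.0086, and adjusted p = 0.56 with an estimated correlation). Markers of endothelial cells (median -0.16, adjusted p = 0.66), fibroblasts (-0.30, adjusted p = 0.66), melanocytes (0.10, adjusted p = 0.62), muscle (0.02, adjusted p = 0.99) and adipocytes (0.04, adjusted p = 0.66) did not pass, nor did EMT and mesenchymal genes (median -0.02 over 17 genes, adjusted p = 0.79). The EMT result again covers only cells sorted for Epcam.

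**Figure D2:**
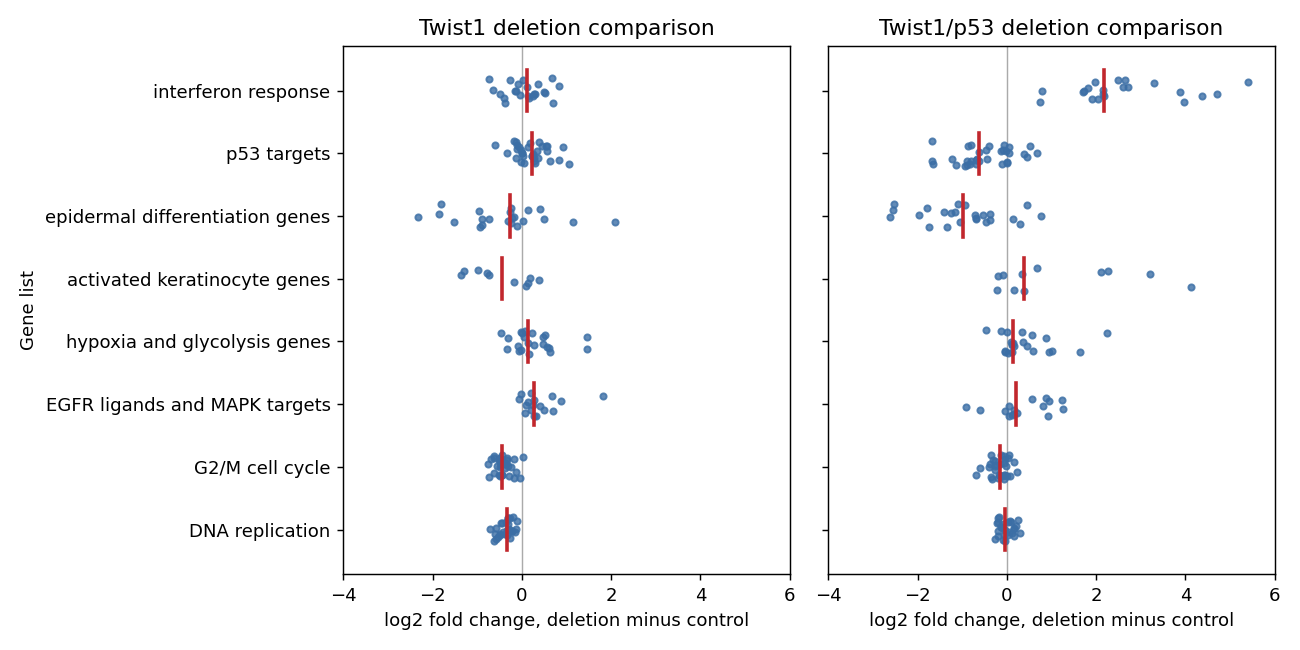
Log2 fold change of each measured member (points) of 8 gene lists (vertical axis), deletion minus control, in the Twist1 comparison (left) and the Twist1/p53 comparison (right), with a red bar at the median of each list. The interferon list has a median of 0.11 on the left and 2.17 on the right, the p53 target list 0.22 and -0.62, and the DNA replication list -0.34 and -0.05.

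The largest differences past the threshold between the 2 deletions were mostly those of interferon-induced genes. In the test of the difference, the Twist1/p53 change minus the Twist1 change, 20 genes were more positive and 3 more negative past the threshold among 13296. Ifi27l2a differed by 5.69 (SE 0.55, limma adjusted p = 0.017), with a change of 6.14 in the Twist1/p53 comparison and 0.45 in the Twist1 comparison. Rtp4 (5.19), Rsad2 (5.10), Oasl2 (4.80), Usp18 (4.13), the double-stranded RNA sensor Ifih1 (4.04), Xaf1 (3.81), the nucleic acid sensor Zbp1 (3.56) and Ifit1 (3.54) followed. Nppb differed by 4.10 (SE 0.40, adjusted p = 0.017), from a change of -3.59 in the Twist1 comparison to 0.50 in the Twist1/p53 comparison. The 3 negative differences were those of Oas1f (-1.85), Atp10d (-1.68) and Fam25c (-1.34). Lor (-5.07), Rgs5 (-4.21), Pde3b (-3.91), Hbb-b2 (-3.60), Cpt1c (-3.23), Col6a1 (-2.69) and Trp53inp1 (-2.62), a p53 target, had larger negative differences that did not pass, with adjusted p between 0.087 and 0.29. The 2 tables come from different array types, so a difference can also hold effects of the array type. Without control 1 or 2 of the Twist1/p53 deletion 10 genes passed in each case, without control 1 or 2 of the Twist1 deletion 11 and 12, and without Twist1 deletion array 1 or 2 the count was 36 and 144, and without Twist1/p53 deletion array 1 or 2 it was 29 and 40.

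Among gene lists, the interferon and p53 target lists had the lowest camera p in the difference, while the median differences of the simple keratin and activated keratinocyte lists were larger than that of the p53 targets. All 22 interferon genes had a positive difference, with a median of 2.28, and 6 passed over all genes and 18 adjusted over the list alone (camera adjusted p = 7.62e-30, fry adjusted p = 0.010, and adjusted p = 0.24 with an estimated correlation). The difference was negative for 26 of 33 p53 targets, with a median of -0.80, and 11 were more negative adjusted over the list alone (camera adjusted p = 1.42e-08, and adjusted p = 0.55 with an estimated correlation). Read from the probe set chosen across both tables, Mdm2 had a change of 0.81 after Twist1 deletion and -0.83 after Twist1/p53 deletion (difference -1.64, SE 0.23, adjusted p = 0.076). Ccng1 differed by -1.39 (SE 0.25, adjusted p = 0.13), Ak1 by 0.98 (SE 0.39) and Cdkn1a by -0.30 (SE 0.18, adjusted p = 0.62). DNA replication (26 of 27 positive, median 0.34, camera adjusted p = 1.40e-05) and G2/M genes (27 of 31 positive, median 0.30, adjusted p = 4.65e-04) were less reduced in the Twist1/p53 comparison, each with adjusted p = 0.61 with an estimated correlation. The spike-in and 3' to 5' values differed between the groups of the Twist1 table (spike-ins 1.33 higher after deletion, Gapdh 0.04 and 0.03 against 0.22 and 0.30). In the Twist1/p53 table Gapdh lay between -0.04 and 0.06 in all 4 arrays. The spike-ins there lay between 3.73 and 3.77, under the lower quartile of all probe sets in each array (3.84 to 3.86). They therefore do not show whether the amounts of RNA were equal. These values stand beside every list of the difference. Among the cell-cycle genes Aurkb differed by 0.96 (SE 0.25), Orc1 by 0.87 (SE 0.27), Chaf1b by 0.77 (SE 0.20) and Nusap1 by 0.64 (SE 0.21). The G2/M list did not pass without Twist1/p53 deletion array 1 (median 0.12).

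Further lists differed between the deletions at higher camera p, and with an estimated correlation their adjusted p lay between 0.55 and 0.69. The 10 activated keratinocyte genes had a median difference of 1.26 (adjusted p = 0.0016), with S100a9 at 3.46 (SE 0.84) and S100a8 at 3.26 (SE 0.79). The hypoxia list (0.22, adjusted p = 0.016) held Bnip3 (1.03, SE 0.16) and P4ha2 (1.03, SE 0.24) but also Adm (-2.01, SE 0.59), and the cytokine list (0.38, adjusted p = 0.038) held Cxcl5 (3.40, SE 1.21) and Il6 (2.56, SE 0.62). Negative medians were found for NRF2 targets (-0.53, adjusted p = 0.027), with Gclc at -1.31 (SE 0.47) and Taldo1 at -0.56 (SE 0.16), for simple and mucosal keratins (-1.49, adjusted p = 0.027), with Krt8 at -1.84 (SE 0.56) and Krt7 at -1.15 (SE 0.29), and for epidermal differentiation genes (-0.48, adjusted p = 0.044), with Lce1a1 at -1.43 (SE 0.36). Of these calls only that of the activated keratinocyte list held without each array in turn. The epidermal differentiation median turned to 0.24 without Twist1 deletion array 1 and to 0.23 without Twist1/p53 deletion array 1, and the list did not pass without control 2 of the Twist1 deletion (-0.26) or of the Twist1/p53 deletion (-0.37). The NRF2 list did not pass without Twist1 control 1 (-0.41), Twist1 deletion array 1 (-0.20), Twist1/p53 control 2 (-0.48) or Twist1/p53 deletion array 1 (-0.37). The simple keratin list did not pass without Twist1 control 1 (-1.15), Twist1 deletion array 1 (-1.46) or 2 (-1.31), or Twist1/p53 deletion array 2 (-1.12). The cytokine list did not pass without Twist1 control 1 (0.34), Twist1 deletion array 1 (0.09), Twist1/p53 control 1 (0.25) or Twist1/p53 deletion array 1 (0.22), nor the hypoxia list without Twist1 deletion array 2 (0.12) or Twist1/p53 deletion array 2 (0.24).

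Across 13296 genes the log2 fold changes of the 2 deletions had a Pearson correlation of 0.33 and a Spearman correlation of 0.29. Genes are not independent replicates, so no p-value is given. The controls of the 2 comparisons are different arrays. Esr1, Gypc and Eif2s3y were called as higher and Xist as lower in both, and Gypc rose by 3.09 (SE 0.16, adjusted p = 0.0094) in the Twist1/p53 comparison. At an unadjusted p under 0.05 with groups that did not overlap, 135 genes were higher in both deletions against 40.7 for independent lists, and 209 were lower in both against 88.6. In opposite directions, 15 genes were higher after Twist1 deletion and lower after Twist1/p53 deletion against 48.8, and 28 went the other way against 74.0. Both comparisons share the split by sex-linked genes and the presence of Cre in the deletion mice alone. The shared changes therefore cannot be assigned to the loss of Twist1, also without the X and Y genes. Without the X and Y genes the Pearson correlation was 0.31, and it was 0.08 without Twist1 deletion array 2 and 0.45 without Twist1 deletion array 1.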

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

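The results below were picked out by rules set beforehand, because the change after Twist1/p53 deletion differed from that after Twist1 deletion in the test of the difference. A difference of this kind can also hold effects of the array type, since the 2 tables come from different array types. The gene lists with a positive median difference were interferon response (2.28), activated keratinocyte (1.26), inflammatory cytokines and chemokines (0.38), DNA replication (0.34), G2/M (0.30) and hypoxia and glycolysis genes (0.22). Those with a negative median difference were simple and mucosal keratins (-1.49), p53 targets (-0.80), NRF2 targets (-0.53) and epidermal differentiation genes (-0.48). The genes were Ifi27l2a (5.69), Rtp4 (5.19), Rsad2 (5.10), Oasl2 (4.80), Usp18 (4.13), Nppb (4.10), Ifih1 (4.04), Xaf1 (3.81), Zbp1 (3.56), Ifit1 (3.54), Oas1f (-1.85), Atp10d (-1.68) and Fam25c (-1.34).

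Other values were picked out because they lie in data that the gene comparisons leave aside. The poly-A spike-in probe sets of the Twist1 table were 1.33 higher on the log2 scale in the deletion arrays than in the controls. Among the probe sets without exactly 1 listed gene, 4 were higher past the threshold in the Twist1 comparison (of 10092, with 1 lower) and 79 in the Twist1/p53 comparison (of 16115, with 117 lower).

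The sex-linked genes separate the groups in the same way in both comparisons, so sex alone would raise interferon genes in both, but the interferon list had a median of 0.11 in the Twist1 comparison (quartiles -0.22 and 0.33) and 2.17 in the Twist1/p53 comparison (quartiles 1.92 and 3.31). Leukocytes among the sorted cells would raise leukocyte markers with it, but the 19 measured of 27 immune cell markers had a median of 0.10 (quartiles -0.03 and 0.54). However, 14 were higher, as were 10 of the 13 whose groups did not overlap, by the most for Cd74 (2.40), H2-Ab1 (1.90), H2-Aa (1.69) and Cd14 (1.34). Both tests were chosen after the result was seen. The first speaks against sex as the only cause of the rise. The second speaks against a general rise of leukocytes as the only cause. The marker list mixes several leukocyte types, so a rise of 1 type could leave its median in place. Such a rise, a smaller share of leukocytes and the cause of the higher markers stay open. Loss of p53, a difference between the cohorts, and an effect of sex that needs p53 loss remain open as explanations. The hypothesis that p53 loss may raise interferon genes in these cells could be tested with same-sex littermates that lack p53 alone, Twist1 alone or both, on 1 array type.

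For the lower cell-cycle lists after Twist1 deletion, an explanation written down before its test is that less sample RNA, read from more spike-in signal, shifts these genes. If so, the array with more spike-in of each group would be lower by 0.31 (controls) and 0.36 (deletion) for G2/M genes, against measured medians of -0.0108 and -0.187, and by 0.23 and 0.26 for DNA replication genes, against -0.0753 and -0.136. With only 1 pair of arrays per group this cannot tell whether the amount of RNA contributes. Sex, a test chosen after the result was seen, would lower the lists in the Twist1/p53 comparison as well, unless p53 loss alters its effect. The medians there were -0.15 (G2/M) and -0.0512 (DNA replication), against -0.45 and -0.34. There 25 of 31 G2/M genes (quartiles -0.29 and -0.04) and 15 of 27 DNA replication genes (quartiles -0.16 and 0.10) were lower, so a smaller effect of sex stays open. Because p53 is deleted there too, an effect of sex that p53 loss offsets also stays open. The same holds for the presence of Cre. Fewer dividing tumour cells may be a candidate explanation, beside the RNA quality that the 3' and 5' probe sets show and that was not tested, and counts of cells in S and M phase in sections of same-sex animals could test it.

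The Esr1 signal rose in both deletions in 1 probe set, and the deletion mice carry CreER, which holds a part of the estrogen receptor sequence. In the Twist1 comparison the other 2 Esr1 probe sets differed by 0.32 and -0.24, values that prompted the tests and so do not decide them. Where the probes lie in the gene was not examined, so the transgene, a partial Esr1 transcript and a rise of the gene itself all stay open. Both tests were chosen after the result was seen.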

How the results depend on the processing

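The gene counts rest on small spreads. After Twist1 deletion 5 genes passed, 1 with the 50th percentile filter, 3 with the mean over the probe sets of a gene, 2 without the X and Y genes and 8 at an adjusted p under 0.10. Without a test, 922 genes changed at least 1.5-fold with groups that did not overlap. Leaving out each array moved the count between 0 (without control 1, 523 genes at an unadjusted p under 0.05 in limma) and 56 (without deletion array 1). After Twist1/p53 deletion 246 genes passed, 859 at an adjusted p under 0.10 and 1674 without a test. Leaving out each array moved that count between 0 (without control 1, 1027 genes at an unadjusted p under 0.05 in limma) and 3775 (without deletion array 1). The control arrays are the closer pair in each table, so the error grows without either of them and shrinks without a deletion array, which follows from the construction of the fit. In the difference 23 genes passed, 12 with the 50th percentile filter, 46 at an adjusted p under 0.10, 1337 without a test, 68 in separate fits, and between 10 (without control 1 of the Twist1/p53 deletion) and 144 (without Twist1 deletion array 2). For all other moves of these counts the cause was not tested.

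The fall of Twist1 after Twist1/p53 deletion (-1.19) did not pass without control 1 (-1.13) or control 2 (-1.24), and ranged from -1.28 (without deletion array 2) to -1.09 (without deletion array 1). The correlation between the 2 deletions (0.33) ranged from 0.0772 (without Twist1 deletion array 2) to 0.45 (without Twist1 deletion array 1).

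No label pairs the arrays by number, and the deviations of same-numbered arrays had correlations of 0.03 and -0.02. With the number as a replicate block 0 genes passed in limma after Twist1 deletion (1234 at an unadjusted p under 0.05), 4 after Twist1/p53 deletion, where Twist1 kept its value of -1.19 but did not pass, and 6 in the difference. The E protein and Id list did not pass with the block after Twist1/p53 deletion (median 0.74).

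The list calls depend on the form of the list test, and not only on the correlation assumed within a list. After Twist1 deletion the estimated correlation was -0.058 for the EGFR and MAPK list and -0.091 for the E protein and Id list. Both lie under the preset 0.01, yet both lists lost their camera call. Other lists that lost it had higher estimates, such as 0.54 for the simple keratins after Twist1 deletion. The estimated form takes its degrees of freedom from the few arrays, so these losses do not show that a list was unchanged. With an estimated correlation camera called 0 lists after Twist1 deletion, 0 after Twist1/p53 deletion and 0 in the difference, and fry called 1, 0 and 1. The p53 target medians of 0.22, -0.62 and -0.80 then did not pass in either test. The first ranged from 0.00199 (without Twist1 deletion array 1) to 0.29 (without array 2) and did not pass at the lower value. The list count of the difference, 10, fell to 6 without Twist1/p53 deletion array 1. The epidermal differentiation median of the difference (-0.48) turned to 0.24 without Twist1 deletion array 1 and to 0.23 without Twist1/p53 deletion array 1, and was -1.29 without Twist1 deletion array 2.

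Other settings ended list calls near the threshold. Quantile normalization ended those of immediate early genes (0.14) and adipocyte markers (0.46) after Twist1 deletion, of immune cell (0.07) and sebocyte markers (0.37) after Twist1/p53 deletion, and of epidermal differentiation genes in the difference (-0.50). That last call also ended with median centring (-0.52), the 50th percentile filter (-0.35), the mean over probe sets (-0.45) and rescaled tables (-0.46). The mean over probe sets ended those of hypoxia genes (0.15) and NRF2 targets (-0.47) in the difference, and of E protein and Id genes (0.52) and sebocyte markers (0.28) after Twist1/p53 deletion. The 50th percentile filter ended those of cholesterol genes after Twist1 deletion (-0.21) and cytokines in the difference (0.40). No filter ended that of immune cell markers after Twist1/p53 deletion (0.07), and leaving out the X and Y genes that of cholesterol genes after Twist1 deletion (-0.16). The cause was not tested.

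Genes with small or scattered changes turned sign. After Twist1 deletion Foxm1 (-0.05) read 0.0330 with quantile normalization and ranged from -0.10 (without deletion array 1) to 0.00636 (without array 2), with 0.00537 without control 2. Txnrd1 (0.32) read -0.00473 with the mean over its probe sets. Ckap2 (0.03) ranged from -0.25 (without deletion array 1) to 0.30 (without array 2), with -0.0156 without control 1. Pcna (-0.10) ranged from -0.25 (without deletion array 2) to 0.0382 (without array 1). Krt13 (1.48) ranged from -0.45 (without deletion array 1) to 3.41 (without array 2), with -0.41 without control 1, and Fabp4 (0.81) from -0.74 to 2.35 without the same arrays, with -0.72 without control 1. After Twist1/p53 deletion Cdkn1a (-0.02) read 0.00209 with quantile normalization and ranged from -0.0728 (without deletion array 2) to 0.0297 (without array 1), with 0.00615 without control 2. The cause of these turns was not tested.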

Other observations

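Genes in this paragraph and the next were named after their values had been seen. After Twist1/p53 deletion the rises included the immunity-related GTPases Igtp (3.89, SE 0.22) and Iigp1 (3.44, SE 0.14), the immunoproteasome subunits Psmb8 (2.60, SE 0.13) and Psmb9 (2.16, SE 0.24), and Nlrc5 (2.63, SE 0.25), the activator of MHC class I genes. No separate list of interferon gamma genes was tested. Arg1, an arginase of wound keratinocytes and macrophages, rose by 2.84 (SE 0.15) and Baiap2l1, an adaptor of actin and membranes, by 3.5 (SE 0.13). All had an adjusted p under 0.05 with n = 2 per group, and none of the calls of this comparison held without either control array.

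Beside Col6a1, the falls of the same comparison included the matrix genes Col6a2 (-1.86, SE 0.16), Col5a2 (-1.99, SE 0.19) and the proteoglycan Lum (-1.10, SE 0.11). No list of matrix genes was tested, and the 14 fibroblast markers did not pass (6 higher and 8 lower, median -0.30, adjusted p = 0.66). The secreted Wnt inhibitor Wif1 rose by 2.69 (SE 0.16) and the ligand Wnt4 fell by 1.09 on the log2 scale (SE 0.13). In the Twist1 comparison Col6a2 differed by 0.04 (SE 0.31) and Col5a2 by 0.58 (SE 0.32).

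The arrays of a group differed by unequal amounts. The SD of the gene differences was 0.33 between the controls and 0.51 between the deletion arrays in the Twist1 comparison, with 241 and 735 genes apart by more than 2-fold. In the Twist1/p53 comparison it was 0.19 and 0.47, with 30 and 625 genes. The difference between the 3' and 5' Gapdh probe sets, which grows as RNA degrades or is labelled shorter, was 0.04 and 0.03 in the Twist1 controls and 0.22 and 0.30 in the Twist1 deletion arrays. In the Twist1/p53 table it was -0.03 and 0.06 in the controls and -0.02 and -0.04 in the deletion arrays. The poly-A spike-in means of that table lay between 3.73 and 3.77, under the lower quartile of all probe sets in each array (3.84 to 3.86). They do not show the amount of RNA.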
